A study of Homo sapiens with 8 samples.

How the data were processed

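Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags DNA that nucleosomes leave exposed. The cells were microglia, the resident macrophages of the brain, differentiated from the H1 human embryonic stem cell line and from the WTC11 human induced pluripotent stem cell line. Each line was left resting or was treated with the type I interferon IFN-β at 100 U/ml for 6 h, which gave 4 groups of 2 libraries. The labels number the replicates of a group without saying that they came from separate differentiations. Each group had 1 peak list made from its 2 libraries, so the spread between replicates could not be measured and no p-value was computed.

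Bowtie2, Picard, MACS2, deepTools and the build hg19 were named in the submitters' processing notes, without versions. Per the labels' descriptions, each list holds the optimal peaks by irreproducible discovery rate (IDR) of its group. Whether these came from the true replicates or from pseudo-replicates of pooled reads, and how reads were shifted, filtered or trimmed, is not given in the sources used here. The authors' deposited lists give for each peak summit a fold enrichment over the local background, which is a ratio and belongs to that list alone. The deposited −log10 p and −log10 q values come from the peak caller, and the deposited score ran from 540 to 1000. A score of 540 is what the IDR tool writes at an IDR of 0.05. No read counts came with the lists, so the depth of each library is unknown and a region missing from a list was at most below the calling threshold there.

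Rows of 1 list with the same coordinates were summits of 1 peak and were joined into 1 region that took the highest fold enrichment. No region ended beyond an hg19 chromosome, while 409 to 445 regions per list ended beyond the hg38 chromosome lengths. Coordinates are hg19, counted from 1. Regions of the 4 lists that overlapped by at least 1 bp were merged into a union. Shares of a list are shares of the union regions it holds, which are fewer than its own regions. A region was called gained when the stimulated list of a line held it and the resting list did not, lost in the opposite case, and kept when both held it. Fold enrichment was turned into a percentile within its own list and was never compared between lists. For regions in all 4 lists, the percentile rank among these same regions was taken in each list, and the rank shift was stimulated minus resting.

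Agreement between the lines was set against the number expected if the lines changed independently, within the 100 strata of joint fold-enrichment decile, and against 1000 shuffles within these strata. Intervals of ratios, of differences between medians and of the correlation came from 1000 draws of whole chromosomes, and intervals of shares are 95% Wilson intervals. All of these cover counting error over regions, which are not replicates. Agreement on gains was counted among regions in both treated lists, a basis chosen after the data were examined because the planned one was at fault. Among regions changed in both lines, the odds ratio of same against opposite direction was added after the data were examined. The functions were tested on simulated data with 58145 regions from the present lists. The 6 planted counts were recovered with an error of at most 0.0313%. The matched ratio lay between 0.988 and 1.06 with permuted labels, which permuting alone would bring about. A planted correlation of 0.5 came back as 0.516. Simulated regions went missing regardless of their fold enrichment. The simulation therefore did not check whether matching on fold enrichment removes the calling noise of weak regions.

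The regions named in the text use the counts and ranking of a rule set before the data were examined. That rule named genes by their promoter regions and took a separate set of distal regions. Here the rule was applied to regions anywhere in the genome, without its limit to promoters. It takes the 12 regions gained and the 6 lost in both lines with the highest lower percentile of the 2 lines, 12 and 6 regions with the largest shared rank shift up and down, and 6 regions per line. An hg19 sequence and gene annotation were not used here. The planned results on promoters, gene lists (interferon-stimulated genes, MHC, microglia identity, Alzheimer risk loci and markers of other cell types), exons and introns, and motifs were therefore not analysed here, and no region was given a gene name. Alternatives varied the overlap, the peak threshold, the list length, the merging distance and the ranking value. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 served as a check of the overlap code. Whether replicate numbers pair libraries across groups was not checked, since the lists hold no values per replicate.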

Results

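The data comprised 4 lists of accessible chromatin regions, 1 for each combination of cell line (H1 or WTC11) and state (resting or treated with IFN-β, an antiviral cytokine). Each list summarised 2 ATAC-seq libraries. Resting H1 microglia had 93635 regions, which covered 62.0 Mb, and IFN-β-treated H1 microglia had 89551 regions, which covered 60.3 Mb. Resting WTC11 microglia had 88160 regions over 51.8 Mb, and treated WTC11 microglia had 79378 regions over 46.5 Mb. The median region was 597 and 607 bp wide in H1 and 516 and 515 bp wide in WTC11. Between 37.9% and 47.1% of regions held more than 1 summit. The median fold enrichment over local background was 8.07 and 7.89 in the H1 lists and 11.1 and 11.04 in the WTC11 lists, each on the scale of its own list. Read depth is unknown for these lists, and with 1 list per group no difference has a replicate check other than the second cell line.

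Merging the 4 lists gave a union of 118586 regions. Of these, 58145 regions (49.0%) were open in all 4 lists, and 23854 were found in 1 list only. The remaining regions were shared by some of the lists, most often by both states of H1 alone (8853 regions) or by all lists except treated WTC11 (7317 regions). After merging, the lists held 92783 (resting H1), 88945 (treated H1), 86680 (resting WTC11) and 77695 (treated WTC11) union regions, and the shares that follow are of these.

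**Figure D1:**
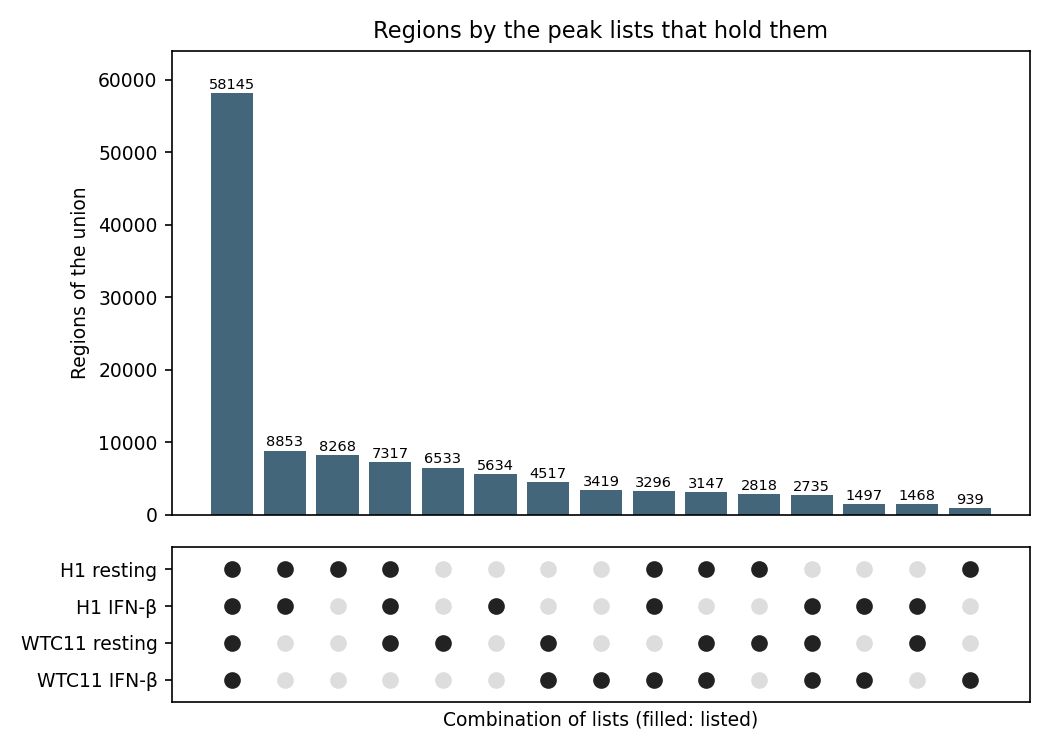
Number of regions of the merged union (bars, linear axis) for each combination of the 4 peak lists that holds them (filled circles). The 58145 regions in all 4 lists form the tallest bar, and the 1497 regions found in both IFN-β lists and in neither resting list are among the shortest.

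The first comparison asked which regions open or close when microglia are exposed to IFN-β. Most accessible chromatin was listed in both states. H1 microglia kept 77611 regions, gained 11334 and lost 15172. The gained regions made up 12.7% of the treated union regions (95% Wilson interval 12.5 to 12.96%), and the lost regions 16.4% of the resting ones (16.1 to 16.6%). WTC11 microglia kept 68544 regions, gained 9151 (11.8% of the treated union regions, 11.6 to 12.01%) and lost 18136 (20.9% of the resting ones, 20.7 to 21.2%). Lost regions thus outnumbered gained regions by 1.34 to 1 in H1 and by 1.98 to 1 in WTC11. The treated list was the shorter one in both lines, and limiting every list to its 79378 strongest regions makes gains and losses nearly equal by construction. H1 then gained 10551 and lost 10511 regions, and WTC11 gained 13757 and lost 14634.

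Gained and lost regions were narrow and weak beside kept ones. As called in the list itself, before merging, gained regions in treated H1 had a median width of 419 bp and kept ones 635 bp, and in resting H1 the lost regions had 415 bp and kept ones 635 bp. In WTC11 the medians were 364 against 539 bp in the treated list and 372 against 563 bp in the resting list. The median gained region stood at the 16.4th percentile of fold enrichment in the treated H1 list and at the 17.8th in the treated WTC11 list. The median lost region stood at the 18.2nd percentile of the resting H1 list and at the 23.4th of the resting WTC11 list. Kept regions had medians between the 55.2nd and the 59.0th percentile. Few changes of listing involved strong regions. In the upper 50% of their list by fold enrichment, H1 had 695 gained and 1120 lost regions, and WTC11 had 755 gained and 2367 lost regions. In the upper 20%, H1 had more gained than lost regions (38 against 28), while WTC11 had 41 gained and 170 lost. Absence from the other list defines a gain or loss and favours weak regions, so these low numbers follow at least in part from the definitions. A strong region that changed but stayed listed was counted as kept. Among regions held by every list, 2870 moved up and 3519 down by more than 20 percentile points in H1. In WTC11 the numbers were 3192 and 4008. How many of these were strong was not counted.

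**Figure D2:**
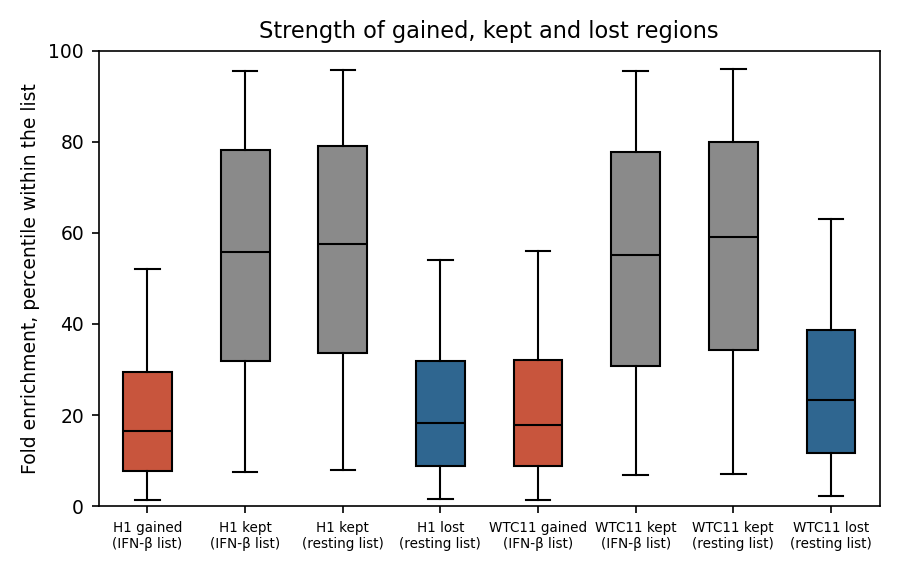
Percentile of fold enrichment within the named list (y axis, 0 to 100) for regions gained, kept and lost after IFN-β in H1 and WTC11 microglia. Boxes show the quartiles, lines in boxes the medians and whiskers the 5th and 95th percentiles over regions; gained and lost regions have medians between 16.4 and 23.4, kept regions between 55.2 and 59.0.

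The second comparison asked whether the same regions responded in both lines, which share no control libraries. A set of 1497 regions was gained in both lines, which is 13.2% of the regions gained in H1 and 16.4% of those gained in WTC11. A further set of 2818 regions was lost in both lines, which is 18.6% of the H1 losses and 15.5% of the WTC11 losses. Among the 65673 regions present in both treated lists, independent gains matched on fold enrichment would have given 627 shared gains. The observed number was 2.39 times as high (interval 2.25 to 2.503), and 1000 shuffles gave 565 to 696. With equal list lengths the ratio was 1.58, and on the basis first planned, regions in neither resting list, it was 0.451, a value that the union forces below 1. Among the 71427 regions present in both resting lists, 1444 shared losses would be expected. The observed number was 1.95 times as high (1.90 to 2.00), and the shuffles gave 1317 to 1533.

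Direction was also shared. Of 6722 regions whose listing changed in both lines, 4315 (64.2%) changed in the same direction and 2407 in opposite directions. Among these 6722 regions only, H1 gained 61.5% (59.5 to 63.4%) of the 2436 that WTC11 gained. Of the 4286 that WTC11 lost, H1 gained 34.3% (32.8 to 35.7%). The odds ratio was 3.06 (2.69 to 3.48). Strong regions mostly changed in the same direction. In the upper 50% of both lists that held them, 77 regions were gained in both lines and 86 were lost in both, against 13 gained in H1 and lost in WTC11 and 5 in the opposite case.

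The strongest region gained in both lines lay on chromosome 1 from 213243565 to 213244226. It stood at the 88.4th percentile of the treated H1 list and the 87.2nd of the treated WTC11 list, and neither resting list held it. It was followed by regions on chromosome 3 (121150689 to 121151512, at the 85.9th percentile in both lists), chromosome 6 (117016569 to 117017007, 87.7th in H1 and 84.8th in WTC11) and chromosome 7 (44662077 to 44662974, 86.1st and 81.9th). A region on chromosome 9 (3385913 to 3386285) reached the 99.3rd percentile in treated WTC11 and the 81.6th in treated H1. A second region on chromosome 1 (180774260 to 180774835) stood at the 81.3rd and 86.0th percentiles. The other 6 named gains lay on chromosome 10 (112789802 to 112790480), chromosome X (96489722 to 96490092), chromosome 3 (101070727 to 101071382), chromosome 4 (176973819 to 176974343) and chromosome 5 (137738384 to 137738770 and 101789310 to 101789914). The lower of their 2 percentiles was between 73.5 and 77.7.

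The strongest region lost in both lines lay on chromosome 6 from 158663514 to 158663975, at the 83.6th percentile of resting H1 and the 87.0th of resting WTC11. The next were on chromosome 14 (34228365 to 34228794, 77.4th and 79.4th percentiles) and chromosome 2 (52656035 to 52656765, 75.7th and 78.3rd). Losses on chromosome 11 (79305631 to 79306243), chromosome 4 (12521060 to 12521396) and chromosome 1 (182621774 to 182622445) followed, with a lower percentile between 68.9 and 72.5.

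Regions that stayed open in all 4 lists also changed their standing after IFN-β. Their rank shifts had a standard deviation over regions of 12.5 percentile points in H1 and 13.4 in WTC11. The shifts of the 2 lines correlated across the 58145 regions with a Spearman rho of 0.231 (0.209 to 0.246), and 58.4% had the same sign. A total of 519 regions moved up by more than 20 points in both lines, where 228 would be expected from independent shifts at matched mean rank. A total of 880 moved down in both lines, where 339 would be expected. Opposite shifts of this size were rarer than expected, with 108 regions up in H1 and down in WTC11 (277 expected) and 115 in the reverse case (274 expected). Ranking by −log10 p instead of fold enrichment turned the balance of the 2 directions, with 641 regions up and 576 down, so that 52.7% of shared shifts were upward instead of 37.1%.

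**Figure D3:**
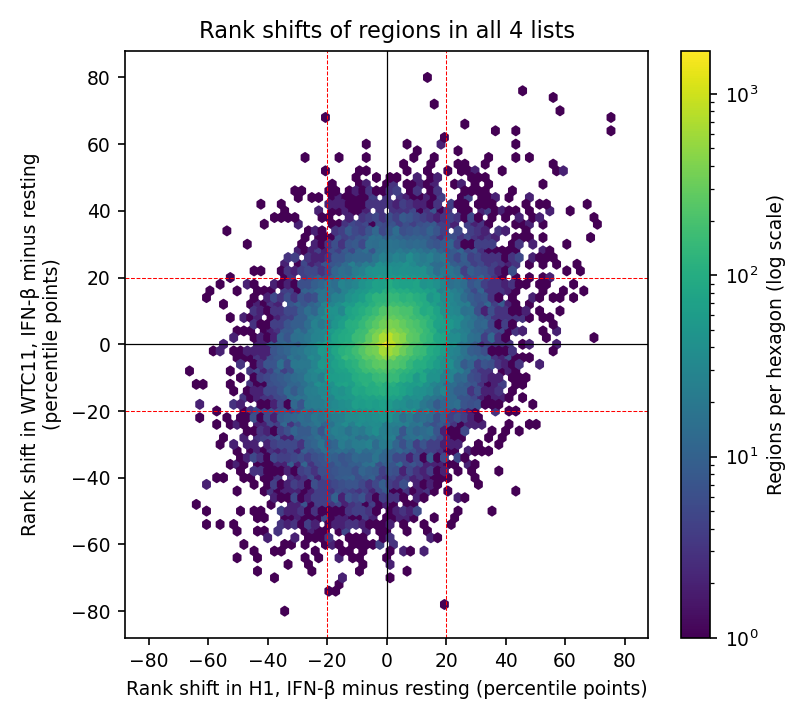
Rank shift after IFN-β in H1 (x axis) and in WTC11 (y axis), in percentile points, for the 58145 regions in all 4 lists; colour gives regions per hexagon on a log scale and dashed lines mark 20 points. The upper right corner holds 519 regions and the lower left 880, against 108 and 115 in the corners of opposite sign.

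The region with the largest shared upward shift lay on chromosome 5 from 50006947 to 50007787. It moved from the 8.11th to the 83.9th percentile in H1 and from the 21.4th to the 88.7th in WTC11. A region on chromosome 4 (40765095 to 40765799) moved up by 75.03 points in H1 and 64.8 in WTC11, and another on chromosome 4 (78656056 to 78656575) by 58.7 and 70.7 points. On chromosome 9, a region from 79018130 to 79018678 moved up by 55.3 and 74.0 points, and one from 2125689 to 2126528 by 60.0 and 52.2 points. Regions on chromosome 1 (209161745 to 209162721, 56.1 and 54.8 points), chromosome 13 (90945955 to 90946629, 58.7 and 52.5 points) and chromosome 20 (9031846 to 9032966, 57.9 and 51.7 points) shifted by similar amounts. Smaller shared shifts of 44.6 to 49.0 points were found on chromosome 8 (81015390 to 81016098), chromosome 10 (120698697 to 120699544), chromosome 3 (61167577 to 61168881) and chromosome 6 (140224766 to 140225721). When fold enrichment was summed over summits, the shared shift, the smaller of the 2 lines, fell under 20 points for the regions on chromosome 10 (17.1) and chromosome 3 (10.8). It went to 21.8 for the region from 40765095 on chromosome 4, 26.8 for that on chromosome 1, 30.2 for that on chromosome 8 and 79.8 for that on chromosome 13.

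Of the 6 named downward shifts, 3 were on chromosome 2. The region from 176053220 to 176053890 shifted by -56.5 points in H1 and -53.5 in WTC11. The region from 191835306 to 191836353 went from the 62.0th to the 1.64th percentile in H1 and from the 76.6th to the 23.4th in WTC11. The region from 165863811 to 165864426 shifted by -51.5 and -53.0 points. The others lay on chromosome 6 (9994318 to 9994913), chromosome 8 (58573519 to 58574363) and chromosome 14 (79600425 to 79601177), with shared shifts between -50.0 and -49.4 points. With summits summed, the shared shift was -23.4 for the region from 176053220 on chromosome 2 and -29.2 for that on chromosome 8.

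Changes were spread over all autosomes, and chromosome 19 stood apart for its small losses. It lost 12.6% of its resting regions in H1 (11.2 to 14.1%) and 13.1% in WTC11 (11.8 to 14.6%), the lowest share of the 22 autosomes in each line. Its part of all regions was 2.22% in resting and 2.40% in treated H1, and 2.51% in resting and 2.72% in treated WTC11. Gains on chromosome 19 differed between lines, at 15.5% (14.0 to 17.1%) of treated H1 regions and 10.5% (9.30 to 11.9%) of treated WTC11 regions. Chromosome 22 had the highest gained share in H1, 18.6% (16.2 to 21.3%), and 11.5% (9.59 to 13.7%) in WTC11. These shares were neither matched on fold enrichment nor repeated at equal list lengths. Most gained and lost regions were weak, so a chromosome's share of weak regions could set them.

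**Figure D4:**
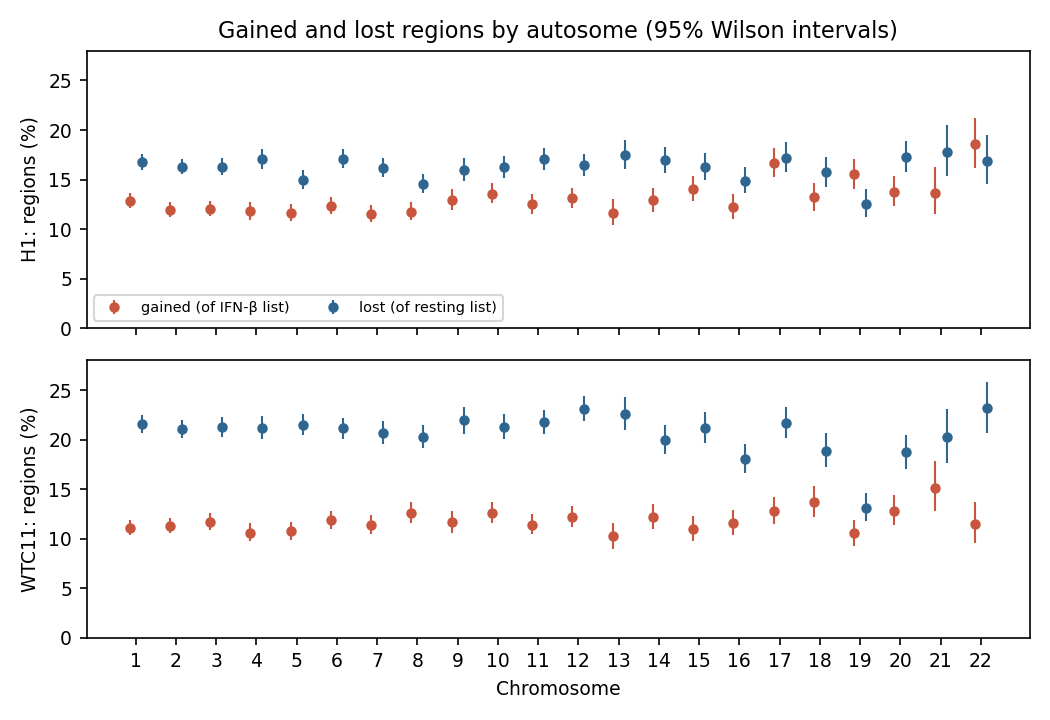
Percent of treated regions gained and of resting regions lost after IFN-β on each autosome, in H1 (upper panel) and WTC11 (lower panel), with 95% Wilson intervals. Chromosome 19 has the lowest lost share in both lines, 12.6% and 13.1%.

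The third comparison set microglia from the embryonic stem cell line against those from the induced pluripotent line. In the resting state the lines shared 71427 regions, which is 77.0% of the H1 union regions (76.7 to 77.3%) and 82.4% of the WTC11 union regions (82.1 to 82.7%). After IFN-β they shared 65673 regions, 73.8% of the H1 union regions (73.5 to 74.1%) and 84.5% of the WTC11 union regions (84.3 to 84.8%). Of the regions open in either line, 66.1% were common at rest and 65.0% after treatment. The 2 states of 1 line had more in common, with 74.5% in H1 and 71.5% in WTC11. These percentages were not repeated at equal list lengths. Line cannot be told apart here from differentiation or library preparation, since each line has 1 list per state. Median region width also followed line, at 597 and 607 bp in H1 and 516 and 515 bp in WTC11. Both states of H1 held 8853 regions that neither WTC11 list had, and both states of WTC11 held 4517 regions that neither H1 list had. The H1 lists were the longer ones, and with equal list lengths these numbers were 6489 and 5340.

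These line-specific regions had lower median percentiles than kept regions and higher ones than those that came or went with IFN-β. By definition, line-specific regions were listed in both states of their line, whereas gained or lost regions were missing from the resting or the treated list. Being listed in both states favours stronger regions, so the higher medians follow at least in part from these definitions. Whether line differences involve stronger regions than IFN-β changes was therefore not tested. The medians of line-specific regions stood at the 29.6th percentile of resting H1 and the 33.4th of resting WTC11. In the treated lists they were lower, at the 25.8th and 28.7th. The upper 50% of the list held 22.0% and 28.1% of line-specific regions at rest, and 16.1% and 21.1% after treatment. The strongest ranked near the top of their lists. The leading H1 regions included 3 on chromosome 7 (64126075 to 64127066, 56173700 to 56174662 and 64254505 to 64255457) and 2 on chromosome 19 (57018773 to 57019751 and 44905258 to 44905977). The last was on chromosome 9 (83279063 to 83280006). All 6 stood at or above the 98.2nd percentile of both H1 lists. The leading WTC11 regions lay on chromosome 2 (114360787 to 114361944 and 225579029 to 225579566), chromosome 10 (42862535 to 42863734), chromosome 9 (70717719 to 70718109 and 44163873 to 44164295) and chromosome 3 (111520971 to 111521641). All 6 stood at or above the 96.3rd percentile of both WTC11 lists.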

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

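The ratios for opposite changes, and the basis on which shared gains were counted, were chosen after the results were seen. Results stood out here when the 2 lines moved in opposite directions after IFN-β, and the difference between the lines was not tested, since each line has 1 list per state. A total of 1468 regions were gained in H1 and lost in WTC11, and 939 were lost in H1 and gained in WTC11. Among regions in all 4 lists, 108 moved up by more than 20 percentile points in H1 and down by more than 20 in WTC11, and 115 did the reverse.

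Opposite changes of listing, matched on fold enrichment in the same way as shared changes, were 1.41 and 1.67 times the number expected from independent lines, and unstable listing was not separated from lines that respond differently. The bound of 1.5 set for the shared ratios does not by itself exclude calling noise, and with equal list lengths the ratio for shared gains went from 2.39 to 1.58, while that for shared losses went from 1.95 to 1.98. Regions lost in 1 line and kept in the other had a median shift of -1.90 points in WTC11 and -3.13 in H1. Regions kept in both lines had 0.517 and 0.713. Here shifts were ranked among all regions kept in the line measured, 68544 in WTC11 and 77611 in H1. Lost regions were weaker than kept ones as a class, and the comparison was not matched on strength. A downward drift of weak regions could give these values of the lost regions, so weak regions stay open as a cause of shared losses. Regions gained in 1 line and kept in the other had 1.56 points in WTC11 and 1.16 in H1. The difference between gained and lost regions was 3.46 points in WTC11 (2.61 to 4.45) and 4.29 in H1 (3.78 to 4.73). In WTC11, 57.9% of these gained regions (56.0 to 59.7%) shifted up, against 53.3% of kept regions. In H1 the shares were 55.8% (54.1 to 57.5%) and 54.2%. Gained regions were weak as a class too, with medians at the 16.4th percentile in treated H1 and the 17.8th in treated WTC11. Their upward shifts argue against a downward drift common to all weak regions. Without kept regions of equal strength, the difference cannot be divided between gains and losses. A response to IFN-β common to both lines could give this difference, although gained regions lay closer to kept regions than lost ones did. A difference in library quality between the states of both lines stays open, untested without read depth.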

How the results depend on the processing

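The −log10 q minimum of 50, the count of regions in both lists as the basis for gains, the odds ratio of direction and the removal of chromosomes X and Y were chosen after seeing the data. No paired analysis was possible because each group has 1 list made from both of its replicates, so no replicate could be blocked or left out. The planned settings for promoter windows, distal regions, gene lists and motifs were not run, since they need an hg19 annotation or sequence. A −log10 q minimum of 5 removed under 100 regions from any list and is no real test, and merging within 150 bp kept all 13 results close. With equal list lengths, WTC11 gained 13757 regions, the ratio for shared gains was 1.58 and the odds ratio 3.93; gains and losses are then nearly equal by construction. At a −log10 q of at least 50, H1 gained 4810 and lost 9118 regions, and WTC11 gained 3219 and lost 12185. Under this minimum 583 were gained in both lines, and the lines shared 42268 treated regions. The ratios for shared gains and losses were then 4.56 and 2.62, and the odds ratio 8.69. Counting only changed regions in the upper 50% of the list that holds them, against the whole other list, H1 gained 695 and lost 1120, WTC11 gained 755 and lost 2367, and 77 were gained and 86 lost in both lines. Under that setting the ratios were 14.1 and 3.59, the odds ratio 102, the shared regions 34908 at rest and 32125 after treatment, and the line-specific regions 1022 in H1 and 676 in WTC11. Requiring 50% reciprocal overlap gave ratios of 2.13 and 1.79 and an odds ratio of 2.33. Without matching on strength, the ratios were 4.85 for gains and 3.33 for losses. The basis first planned for gains, regions in neither resting list, gave 0.451, below 1; the union holds no region missing from all lists, so this basis forces the lines apart. Ranking by −log10 p left 576 regions down in both lines, and summing fold enrichment over summits gave a correlation of 0.168. All 30 named gained, lost and line-specific regions kept their class under the 4 settings tried. Settings that shorten the lists cannot bring in a missing region, and these regions were picked as strong, so this is hardly a test. The 50% reciprocal overlap was not tried on them. When summits were summed, 10 of 12 upward regions stayed past 20 points, all but those on chromosome 10 (17.1) and chromosome 3 (10.8). The cause of the other shifts was not tested. Depth limits each absence: a region missing from a list is below a threshold of unknown read number.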

Other observations

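The windows of line-specific regions, the match on local density and the test of downward regions under it were chosen after the result was seen, and the rule for neighbouring regions was widened then. Line-specific regions were unevenly spread over the genome. Over the 22 autosomes there were 8579 H1-specific and 4361 WTC11-specific regions, a ratio of 1.97, and with equal list lengths 6257 and 5173, a ratio of 1.21. Chromosome 19 had a ratio of 0.799 (119 against 149) and chromosome 22 of 0.831 (69 against 83), which were 0.584 and 0.602 with equal list lengths. At equal lengths, chromosomes 21 (0.618), 17 (0.913) and 20 (0.972) also had more WTC11-specific than H1-specific regions. Chromosome 8 had 2.73 (620 against 227) and chromosome 15 had 2.71 (339 against 125), which were 1.81 and 1.68 with equal list lengths. Within chromosome 19, the first 10 Mb held 8 H1-specific and 42 WTC11-specific regions, so that 16.0% were H1-specific (8.34 to 28.5%), and 12.5% with equal list lengths. From 30 to 40 Mb the same chromosome held 39 and 12, or 76.5% (63.2 to 86.0%), and 66.7% with equal list lengths. Among windows of 10 Mb with at least 40 line-specific regions, the first 10 Mb of chromosome 19 were the least H1-specific. The most H1-specific window was on chromosome 8 from 10 to 20 Mb, with 45 against 7, and 31 against 7 with equal list lengths. Intervals of windows are for single windows and do not allow for picking the extremes.

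Rank shifts correlated between the lines, and a trend with region width or strength common to both treated lists was one candidate explanation. After the mean shift of each stratum of width and mean rank was taken off, rho was 0.218 (0.197 to 0.234) against 0.231 before. Such a trend therefore does not account for the correlation. Other differences between resting and treated libraries, and a response to IFN-β, stay open.

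More regions were lost than gained in both lines, and a less sensitive treated list is a candidate cause. Among regions in the upper 50% by fold enrichment, the ratio of lost to gained was 1.61 in H1 (1.43 to 1.81) and 3.14 in WTC11 (2.77 to 3.50), so the H1 interval spans the bound of 1.5; a less sensitive list would also miss some strong regions, which weakens this test. In the upper 20% the ratio was 0.737 in H1 and 4.15 in WTC11. Lower sensitivity and net closing cannot be told apart here, since list length follows treatment in both lines and read depth is unknown.

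A hypothesis that neighbouring regions respond together was tested on 2016 regions that were gained or moved up by over 20 points in both lines, and on 3698 that were lost or moved down. Of the upward set, 12.9% had another member within 50 kb, and of the downward set 17.9%. In 1000 random sets matched on fold enrichment the central 95% ran from 13.2 to 17.5% and from 22.1 to 25.7%, so both shares were lower than random. The bound set beforehand for rejecting the hypothesis was a share inside these ranges, and a share below them met neither bound. It was counted against the hypothesis only after the values were seen, since responding together would raise the share. These random sets ignored the local density of regions. Matching density lowered the random median from 15.2 to 11.9% for the upward set and from 23.9 to 16.0% for the downward set. The shares below random therefore cannot decide the hypothesis.

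With local density of regions matched too, the upward share lay inside the random range (9.97 to 13.6%). The downward share of 17.9% lay above its range (14.6 to 17.5%) and below the highest random set (18.6%), so a small excess among downward regions stays open. Upward regions formed groups of at most 3 within this spacing, and the groups differed in density. On chromosome 10 from 79382611 to 79398507, 3 of 4 union regions were gained in both lines. On chromosome 14 from 61991228 to 62051433 it was 3 of 12.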
